A study of Homo sapiens with 3 samples.

How the data were processed

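RNA from khES3 cells in complete, leucine-deprived and lysine-deprived medium was measured on 1 array per condition. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was made from 100 ng of it with the manufacturer's 3′ in vitro transcription kit. The deposited values are signal intensity per probe set on a linear scale, and the authors made them with MAS5, per the submitters' processing notes. The MAS5 version and its settings are not given in the sources used here. On each array the mean of the values after trimming 2% at either end was 500.1, so the deposited intensity values had been scaled to a common mean. Values ran from 0.11 to 175233. Such scaling removes any difference in total mRNA between arrays, and a change of many genes in one direction would shift the others the opposite way. Detection calls were not used here, so dim signals were handled with a floor. Primers that start at the poly-A tail make probe sets far from the 3′ end sensitive to RNA quality.

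Of 54675 probe sets, 62 are controls. Of the other 54613, 41091 name 1 gene in the platform annotation, 1801 name several and 11721 are not named here. For 41037 of the singly named probe sets the Entrez identifier was found in the RefSeq gene table of GRCh38.p14, used for names only, and 0 symbols differed. Values were floored at the 40th percentile of each array's probe sets (54.6, 56.7 and 62.4 for complete, leucine-deprived and lysine-deprived) and taken to log2. Probe sets were kept where the mean over the 3 arrays was at or above the median (23055 naming 1 gene), and a gene took the kept probe set with the highest mean. A 2-fold difference was counted only for genes above the floor on both arrays, and others were given as bounds. No per-sample columns were left unused.

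With 1 array per group no test between groups was possible. For each of 27 gene lists the median difference of its kept members was set beside the medians of 10000 random lists of the same size, drawn within 20 bins of level; a list stood apart where its median lay outside the 2.5 to 97.5 percentile range, which describes these arrays and is not a test across cultures. Of 632 list genes 520 had a kept probe set; the others are on dim or multi-gene probe sets or are not analysed here, among them POU5F1. The lists cover ATF4 targets, amino acid handling and sensing, stress pathways, metabolism, ribosomes, cell cycle, pluripotency, germ layers, trophoblast and feeder cells. Some share members: 7 synthetases, 7 transporters and 6 serine, glycine and folate-cycle genes are also ATF4 targets. The 3 arrays with no effect were simulated 100 times with noise from genes of like level. For ATF4 and G2/M genes with several kept probe sets, the median over their next-brightest ones was set beside 10000 random draws of next probe sets of like level. Agreement between probe sets of a gene was given with exact Clopper-Pearson 95% intervals, which treat genes as independent.

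The genes named were chosen by rule: a fixed set of 10 anchor genes, the 10 highest and 10 lowest genes per deprivation and the 5 highest and 5 lowest between deprivations (above the floor, with all kept probe sets of the gene differing the same way), up to 4 members per list with the largest mean absolute difference, and up to 3 bounds per direction. Genes with numbered provisional names and sex-linked marker genes were left out. The comparisons, lists, rule and alternatives were fixed before the data were examined, except the counts among brighter genes and a metallothionein list. Alternatives were median centring, quantile and cyclic loess normalization, floors at the 20th and 60th percentile or log2(value + 32) without a floor, no level filter or the 70th percentile, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridising or shared, thresholds of 1.5- and 3-fold, unmatched random lists and lists without ATF4 targets.

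The calculations were tested on simulated arrays for leucine-deprived over complete medium (13077 genes), with noise from the leucine-minus-lysine differences of probe sets before flooring. Of genes seeded 3-fold higher 83.7% (of 98) came out at least 2-fold higher, and of those seeded 3-fold lower 91.3% (of 92). Of unchanged simulated genes 11.3% passed 2-fold, bounds included, and 0.565% of the brighter ones. A list seeded at 1 had a median of 0.94. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used. The number of arrays limits the precision.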

Results

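Gene expression was measured in khES3, an established human embryonic stem cell line, kept undifferentiated and cultured for 5 hours in complete medium, in medium without leucine or in medium without lysine. Leucine and lysine are essential amino acids, which human cells cannot make. Each of the 3 conditions had 1 Affymetrix array of 54675 probe sets, so the differences below have no replicate check and no p-values. The median signal was 82.8 on the complete-medium array, 90.6 on the leucine-deprived array and 98.2 on the lysine-deprived array. In all, 12961 genes had a probe set above the level filter, and across their 23055 probe sets the arrays correlated with r = 0.966 (leucine-deprived and complete), 0.953 (lysine-deprived and complete) and 0.957 (leucine-deprived and lysine-deprived). Probe sets are not independent replicates. Differences are in log2 signal, where 1 is a 2-fold difference. The only error these arrays give is the SD of the difference between probe sets of the same gene, over 5981 genes: 0.49 for leucine-deprived over complete, 0.57 for lysine-deprived over complete and 0.58 for leucine- over lysine-deprived. It leaves out the spread between cultures.

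The first comparison asks what leucine removal did to the transcriptome. On the leucine-deprived array the gene that stood highest over complete medium was INHBE, an activin subunit gene (21.5-fold higher), which is not in the ATF4 list below. Of the other 9 highest, 6 are in that list of targets of ATF4, the transcription factor translated when amino acids run short. TRIB3, a pseudokinase gene, was 13.96-fold higher (its other probe set 1.75 on the log2 scale), and DDIT3, which encodes the stress transcription factor CHOP, was 8.87-fold higher. DDIT4, an inhibitor of mTORC1 signalling, was 7.50-fold higher, and CHAC1, a glutathione-degrading enzyme, 6.46-fold higher. STC2 (2.66), a secreted glycoprotein, and ALDH1L2 (2.36), a mitochondrial folate enzyme, are also in the list. The ATF4 target list, fixed beforehand, had a median difference of 1.15 over 45 measured members, above all 10000 random lists matched on level, the highest of which reached 0.20. In this list 23 members were at least 2-fold higher and above the floor on both arrays, and 1 more was at least 2-fold higher as a bound. No member was 2-fold lower, and 43 of 45 lay above 0; KLHL24 (-0.16) and ALDH18A1 (-0.14), singled out after their values were seen, lay below. ASNS, the asparagine synthetase gene, was 1.29 higher and SESN2, a leucine-binding inhibitor of mTORC1, 1.49 higher. ATF4 itself was 0.62 higher.

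The rest of the 10 highest after leucine removal were G0S2 (3.50), an inhibitor of fat breakdown, TAC1 (2.47), the substance P precursor, and TSC22D3 (2.46, other probe set 1.15), a glucocorticoid-induced gene. In all, 327 genes were at least 2-fold higher and 176 at least 2-fold lower, of 12297 genes above the floor on both arrays. A further 166 were higher and 159 lower as bounds, which makes 6.39% of genes past 2-fold. Among the 6481 genes at or above the median level, 53 were higher and 4 lower (0.880%). This level averages all arrays, which favours higher over lower genes in counts of brighter genes over complete medium. In simulated arrays 11.3% of unchanged genes passed 2-fold, and 0.565% of brighter ones. The simulated noise came from the leucine-minus-lysine differences of single probe sets before flooring. Between the leucine- and lysine-deprived arrays 8.43% of genes passed 2-fold, bounds included, and 0.370% of brighter ones, so the simulated shares ran high. After flooring, the SD of leucine minus lysine was 0.56 over all genes and 0.29 over brighter ones. For leucine-deprived over complete it was 0.50 and 0.31. Where the brightest probe set of a gene was 2-fold higher, the next probe set was also higher in 74 of 102 genes (72.5%, exact Clopper-Pearson 95% interval 62.8 to 80.9), and in 29 of 30 brighter genes (96.7%, 82.8 to 99.9). For 2-fold lower genes it was also lower in 26 of 48 (54.2%, 39.2 to 68.6), near the even split that unrelated probe sets give. The 10 lowest genes were SOX6 (-2.11), SULF1 (-2.02), PEX39 (-1.98), TMEM132A (-1.94), ARHGAP30 (-1.91), NLRP2B (-1.83), DGCR11 (-1.78), RUSC1-AS1 (-1.71), MATK (-1.71) and KRT8P12 (-1.69). All 10 lay below the median level of kept genes, and 9 of them rest on 1 probe set.

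Of the amino acid handling lists, cytosolic synthetases, transporters and serine, glycine and folate-cycle genes were higher after leucine removal. Only the synthetases stood apart without the members shared with the ATF4 list. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had a median difference of 0.51, with 16 of 17 members above 0; AARS1 was 1.15 higher, CARS1 0.98, GARS1 0.92 and WARS1 0.82. Without the members shared with the ATF4 list the median was 0.34 over 10 genes, still above all random lists. Amino acid transporters had a median of 0.43 over 24 members, above all random lists; SLC7A11, the cystine carrier, was 2.13 higher (lowest probe set 1.33), SLC1A4 1.44 (lowest 0.12) and SLC7A1, the cationic amino acid carrier, 1.21, whereas SLC38A5 differed by -1.23. Without shared members the transporter median was 0.24 over 17 genes, at percentile 97.2, inside the middle 95% of random lists. Serine, glycine and folate-cycle genes had a median of 0.21 over 13 members (percentile 99.5), with MTHFD2 at 1.35, SHMT2 at 1.06 and PSAT1 at 0.93. Without shared members this list too lay inside, with a median of -0.01 over 7 genes (percentile 50.6).

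Further lists stood apart on the leucine-deprived array, where the signal of the 3′ end of ACTB was 7.55 times that of its 5′ end, against 5.44 times on the complete-medium array. Cholesterol synthesis genes were lower, with a median of -0.36 and 15 of 18 members below 0, below all random lists; INSIG1 differed by -0.90, MSMO1 by -0.82, HMGCS1 by -0.79 and IDI1 by -0.76. Heat shock genes had a median of -0.30 over 10 members, also below all random lists, with the co-chaperone genes DNAJA1 at -1.12 and DNAJB1 at -0.97 and with HSPH1 at -0.73. Cytosolic ribosomal protein genes had a median of 0.16, with 50 of 52 members above 0 and above all random lists; RPL10A was 0.44, RPL36A 0.39, RPS23 0.28 and RPLP2 0.06 higher (its other probe set -0.78). The RPL36A and RPLP2 probe sets were dim (level percentiles 20.2 and 25.1), whereas the list's median level percentile was 99.7. Matching in 20 bins of level is coarse that near the top. Many ribosomal protein genes have near-identical copies that probe sets cannot tell apart. Ribosome biogenesis genes had a median of -0.13 (28 members, percentile 1.06), with POLR1C at -0.70, BYSL at -0.61, PES1 at -0.50 and NOP16 at -0.39. Immediate early genes had a median of 0.19 (26 members, percentile 99.6), with ATF3 at 2.21, EGR1 at 2.01, EGR3 at 1.11 and KLF10 at 0.78. FOXO and MondoA targets had a median of 0.31 (9 members, percentile 98.9), with TXNIP, an arrestin-family gene, at 1.26 and ARRDC4 at 0.86.

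Cell cycle lists were slightly lower after leucine removal. The G1/S list had a median of -0.15 over 25 members (percentile 1.15), although CDT1, a replication licensing gene, was 0.95 higher (other probe set 0.01); E2F1 differed by -1.30 (other probe set -0.23), CHAF1B by -0.80 and E2F2 by -0.71. The G2/M list had a median of -0.16 over 25 members (percentile 0.90), with UBE2C at -0.48 and CENPA at -0.37 but PLK1 at 0.34 and KIF20A at 0.01. Germ layer markers were dim. The mesoderm list had a median of 0.54 over 10 members (percentile 98.2), with HAND1 at 1.08 and BMP4 at 0.81 but MSX1 at the floor, with a bound of -0.74. The endoderm and mesendoderm list had a median of -0.55 over 9 members (percentile 1.85), with HHEX at -1.28, LHX1 at -1.20 and CER1 at the floor, with a bound of -1.57, but TBXT at 0.24. These markers lay at a median level percentile of 18.9 and 11.3 among kept genes, and with the floor at the 60th percentile the endoderm median was 0.04, the same as that of all genes. Of the alternatives, 5 put each of these marker lists inside the middle 95%, 3 the FOXO and MondoA list, 3 the serine, glycine and folate-cycle list, 2 the ribosomal protein list, 2 the ribosome biogenesis list, 1 the G1/S list and 1 the transporters.

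The remaining lists had medians inside the middle 95% of random lists on the leucine-deprived array. Pluripotency genes had a median of 0.03 over 24 members, with the core factors NANOG at 0.13 and SOX2 at 0.14, where the lowest SOX2 probe set was -0.56. The cell cycle inhibitor CDKN1A was 0.54 higher, while p53 targets as a list had a median of -0.03 over 23 members. ER chaperones and unfolded protein response genes had a median of -0.07 over 22 members and a mean of 0.03, although HERPUD1 (1.15) and EDEM1 (1.16) were each above 2-fold. Amino acid sensing genes upstream of mTORC1 had a median of 0.01 over 30 members, and leucine and lysine breakdown genes 0.01 over 18. The methionine cycle list had a median of -0.01 over 15 members, with CTH, a cysteine-making enzyme, at 1.21 and MAT2A at -0.38. Medians were 0.04 for mitochondrial synthetases (15 members), -0.10 for glycolysis and HIF targets (25), 0.07 for autophagy and lysosome genes (34), 0.12 for NRF2 targets (10), 0.12 for ectoderm and neural markers (3), 0.22 for trophoblast markers (4) and -0.00 for fibroblast and feeder cell markers (13). Also past 2-fold in these lists were DDIT4 (2.91) and SESN2 (1.49) among sensing genes and SLC7A11 (2.13) and HMOX1 (1.34) among NRF2 targets. TFEB (1.86) was so in the autophagy list and, as a bound, WDR24 (1.48) among sensing genes.

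**Figure D1:**
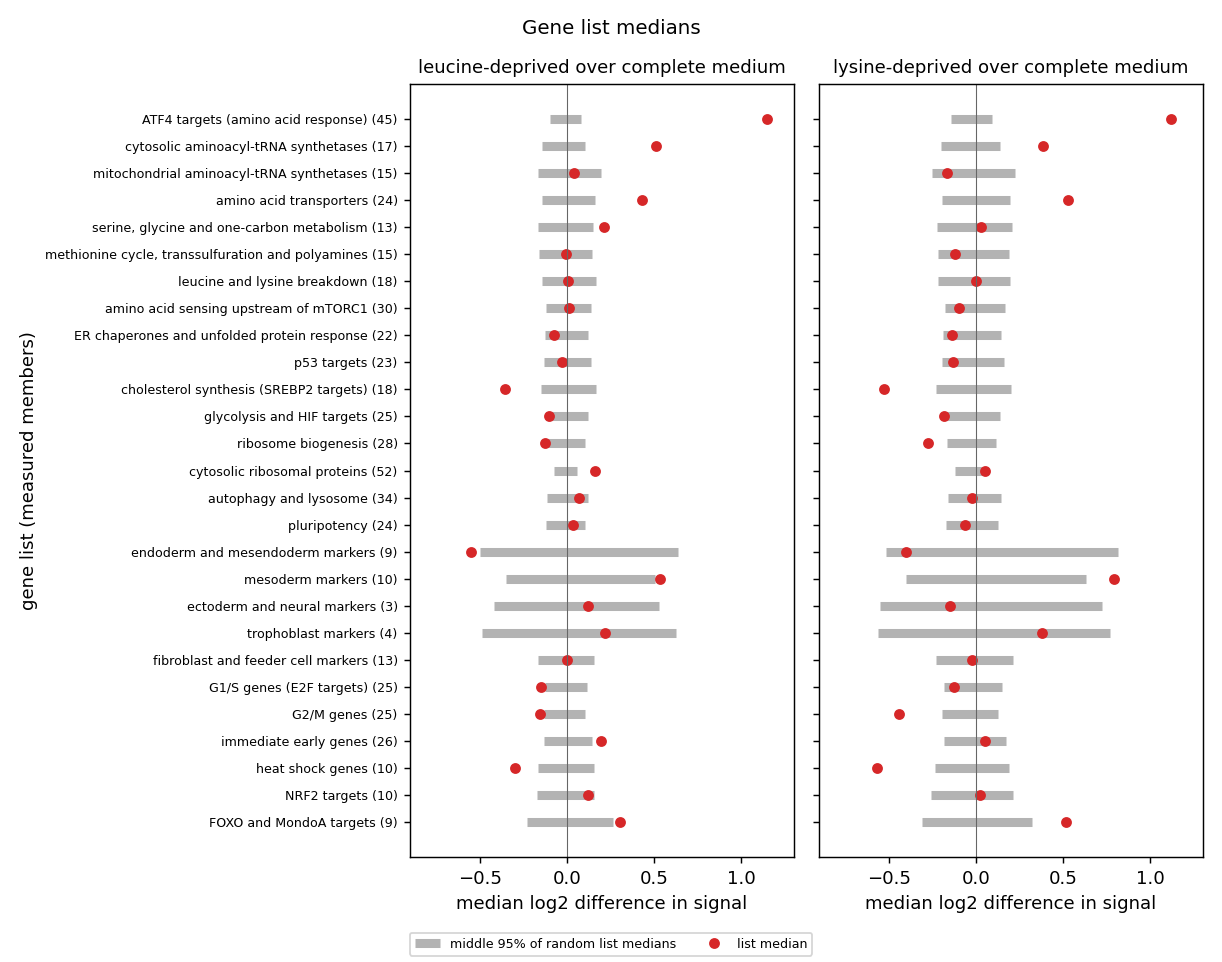
Median log2 difference in signal of each gene list (points) over complete medium, for the leucine-deprived array on the left and the lysine-deprived array on the right, with the middle 95% of medians of 10000 random lists matched on level (grey bars) and the number of measured members in parentheses. The ATF4 target list lies at 1.15 and 1.12, and the cholesterol synthesis list at -0.36 and -0.53.

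The same question was asked of lysine removal. By the naming rule, the genes highest on the lysine-deprived array over complete medium were again INHBE (29.9-fold), TRIB3 (13.5-fold, other probe set 0.55 on the log2 scale), G0S2 (8.93-fold) and DDIT3 (8.70-fold). STC2 (7.70-fold), DDIT4 (7.63-fold), CHAC1 (5.83-fold) and TAC1 (2.52 on the log2 scale) came next, followed by GAL3ST4 (2.47) and CCDC33 (2.43). In complete medium GAL3ST4 and CCDC33 had signals of 65.4 and 54.8, near the floor of 54.6, each on 1 probe set. VEGFA (2.57) and TSC22D3 (2.47, lowest probe set -0.05) were as high. The rule left them out because their probe sets did not all differ the same way. The ATF4 target list had a median difference of 1.12 over 45 members, above all random lists, the highest of which reached 0.21. Here 24 members were at least 2-fold higher and 1, KLHL24, was 2-fold lower (-1.96). ASNS was 1.36, SESN2 1.22 and ATF4 0.80 higher, whereas CDKN1A differed by -0.10. Counted over genes, 516 were at least 2-fold higher and 239 at least 2-fold lower, of 12227 above the floor on both arrays, with 267 higher and 204 lower as bounds. After quantile normalization the split was 445 higher and 326 lower. Among the 6481 brighter genes 90 were higher and 28 lower.

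The next probe set of 2-fold higher genes was also higher in 118 of 176 genes after lysine removal (67.0%, 59.6 to 73.9), and that of lower genes also lower in 38 of 75 (50.7%, 38.9 to 62.4). Among brighter genes these shares were 47 of 56 (83.9%, 71.7 to 92.4) and 11 of 13 (84.6%, 54.6 to 98.1). The 10 lowest genes were SPRYD4 (-2.14), IMPDH1 (-2.06), ABCF3 (-2.03), PEX39 (-2.01), PLK1 (-1.99), PARP14 (-1.94), ZNF71 (-1.86), BICDL1 (-1.84), ZDHHC12-DT (-1.82) and FBP1 (-1.78), each read by 1 dim probe set. For genes at the floor on the complete-medium array, THEM6, LINC01278 and S100P were at least 5.66-, 5.69- and 5.32-fold higher after leucine removal, and LINC00622, CRYGD and SHKBP1 at least 7.26-, 7.15- and 6.34-fold higher after lysine removal. On the lower side the bounds were -2.74 for FGD2, -2.64 for NGEF and -2.38 for ARHGEF11 after leucine removal, and -2.60 for FGD2, -2.47 for INCENP and -2.42 for LPL after lysine removal. Another probe set of FGD2 was higher by 0.42 and 0.88, and another of LPL was higher by 0.02 after leucine and 0.96 after lysine removal.

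Cholesterol synthesis, heat shock and mitotic genes were lower on the lysine-deprived array. The cholesterol list had a median of -0.53, with 17 of 18 members below 0; MSMO1 differed by -1.17, IDI1 by -1.16 and INSIG1 by -1.03. The probe sets of IDI1 ranged from -1.49 to 0.46. Heat shock genes had a median of -0.57 over 10 members (percentile 0.01), with DNAJA1 at -1.50, DNAJB1 at -1.30, HSP90AB1 at -0.65 and HSPH1 at -0.64. The G2/M list had a median of -0.44, with 22 of 25 members below 0; PLK1, a mitotic kinase gene, differed by -1.99, KIF20A by -1.02, CENPA by -0.81 and UBE2C by -0.78. The cholesterol and G2/M medians lay below all random lists. Ribosome biogenesis genes had a median of -0.28 with 26 of 28 members below 0 (percentile 0.03), including POLR1C at -0.74 (other probe set 0.17) and NOP16 at -0.59. Glycolysis and HIF targets had a median of -0.18 over 25 members (percentile 1.95), with ALDOC and PFKFB4 at -0.63 but ADM at 0.72. On this array the signal of the 3′ end of ACTB was 11.2 times that of its 5′ end, against 5.44 times on the complete-medium array.

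Of the amino acid handling lists, synthetases and transporters stood apart after lysine removal, but not without the members they share with the ATF4 list. Synthetases had a median of 0.38 with 12 of 17 members above 0 and transporters 0.53 with 15 of 24 above 0, both above all random lists. SLC7A11 was 2.20 higher (lowest probe set 0.10) and SLC1A4 1.39 (lowest 0.86), whereas SLC38A5 lay at the floor, with a bound of -1.84. Without the shared members neither stood apart: 0.06 over 10 synthetases (percentile 81.1), 5 of them above 0, and -0.09 over 17 transporters (percentile 26.6), 8 above 0. FOXO and MondoA targets had a median of 0.51 over 9 members (percentile 99.9), with ARRDC4 at 1.12, CITED2 at 1.11 and TXNIP at 0.98. The mesoderm list had a median of 0.79 over 10 members (percentile 99.2), with MSX1 at 1.47, BMP4 at 1.27 and MESP1, at the floor in complete medium, at least 1.34 higher, all dim. Ribosomal protein genes had a median of 0.05 over 52 members (percentile 98.1). Of the alternatives, 7 put the ribosomal list inside the middle 95%, 4 the glycolysis list, 3 the mesoderm list, 2 the transporters, 1 the synthetases and 1 the FOXO and MondoA list.

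The other lists lay inside the middle 95% after lysine removal. Pluripotency genes had a median of -0.07 over 24 members; NANOG differed by -0.00 and SOX2 by 0.21 (lowest probe set -1.82), while GDF3, a TGF-beta family gene of undifferentiated cells, differed by -1.45 and NODAL by -0.69. Immediate early genes had a median of 0.05 over 26 members, although ATF3 (2.31, with another probe set at -0.28), EGR1 (1.76) and EGR3 (1.34) were above 2-fold. ER genes had a median of -0.14 over 22 members, with HERPUD1 at 1.07 and SDF2L1 at -1.09. p53 targets had a median of -0.13 (23 members), with TP53INP1 at -1.07. The mTORC1-sensing list had a median of -0.10 and a mean of 0.05 (30 members), and the methionine cycle list a median of -0.12 and a mean of 0.04 (15). Medians were 0.03 for serine, glycine and folate-cycle genes (13 members), -0.17 for mitochondrial synthetases (15), -0.00 for leucine and lysine breakdown with a mean of 0.02 (18), -0.03 for autophagy and lysosome genes with a mean of 0.01 (34), -0.13 for G1/S genes (25), 0.02 for NRF2 targets (10), -0.40 for endoderm markers (9), 0.38 for trophoblast markers (4) and -0.02 for fibroblast and feeder cell markers (13). The 3 measured ectoderm markers had a median of -0.15 and a mean of 0.11. Against their list's median went TBXT (1.41) in the endoderm list, TFEB (2.28) in the autophagy list, CTH (1.36) in the methionine list and, as a bound, WDR24 (2.20) in the mTORC1-sensing list. ALDH1L2 (2.26) and MTHFD2 (1.41) stood high in the serine list and GATA2 (1.33, lowest probe set -0.36) in the trophoblast list. RRAGB (-1.28) and ULK1 (-1.15) were past 2-fold lower, RRAGB as 1 of 2 such genes in the mTORC1-sensing list.

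The overlap of both deprivations was examined next. ATF4 targets stood at nearly equal heights: the differences of the 45 members correlated with r = 0.935 across genes (mean 0.502 and maximum 0.849 in the simulations below), their median leucine-minus-lysine difference was 0.00, and 43 of 45 lay within 0.5 of each other. The median absolute difference between the deprived arrays was 0.11 for these genes, against 0.18 for random genes of like level (middle 95% of 1000 draws, 0.12 to 0.24). At least 2-fold higher on both arrays were 151 genes and at least 2-fold lower 25, with 0 in opposite directions. Both differences share the complete-medium array, and 100 simulations of 3 arrays with no effect gave a mean of 104 genes higher on both (maximum 131) and 104 lower on both (minimum 85); independent lists would share 14.2 and 3.53. The 25 genes lower on both lay below every simulation, so over all genes these simulations are no reliable reference for either count. The simulated noise came from the leucine-minus-lysine differences, whose variance of 0.309 lay between those of leucine-deprived (0.254) and lysine-deprived (0.353) over complete. Among brighter genes it was 0.0866, below both (0.0989 and 0.158), so simulated counts there may be too low.

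Among the 6481 brighter genes, 43 were higher on both deprived arrays, against a simulated mean of 2.16 and maximum of 6, and 2 were lower on both, DNAJA1 and HSPA2, the latter named after its values were seen. Of the 43, 19 belong to the ATF4 list and 24 do not. The level that defines brighter genes averages all arrays. A gene higher on both deprived arrays is thus moved towards this set, and a lower one out of it. TAC1, with a signal of 216 in complete medium, was inside (level percentile 52.2), and RUSC1-AS1, with 925, outside (41.0). The simulated means, 2.16 higher and 2.14 lower, cannot show such an asymmetry. The simulations kept the genes already chosen and added symmetric noise, without choosing again by level. Part of the 43 against 2 may therefore come from how the set was chosen. The differences correlated with r = 0.498 over all genes (simulated 0.507) and 0.681 over brighter genes (simulated 0.498). The covariance was 0.149 over all genes, inside the simulated range (0.133 to 0.151), and 0.085 over brighter genes, above the simulated range (0.040 to 0.046). Without the ATF4 list it was 0.141, also inside the range (0.134 to 0.151), and 130 genes were higher on both, against a simulated maximum of 128. These simulations too gave more genes lower on both (minimum 76) than the 25 seen. Part of any excess may come from the shared array, which 1 control array does not allow to be split.

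**Figure D2:**
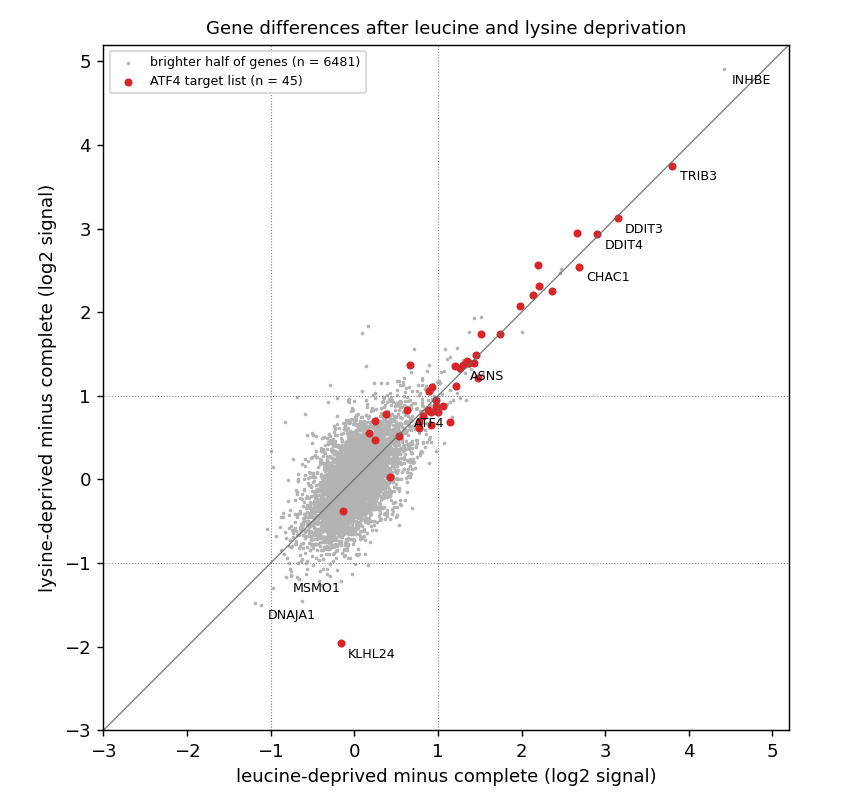
Log2 difference in signal over complete medium for the leucine-deprived array (horizontal) and the lysine-deprived array (vertical), for the 6481 brighter genes (grey) and the 45 measured ATF4 targets (red); dotted lines mark 2-fold and the solid line equal differences. ATF4 targets lie along the line of equal differences, with KLHL24 at -0.16 and -1.96 apart from it.

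Set against each other, the deprived arrays differed most in dim genes. On the leucine-deprived array 236 genes were at least 2-fold higher and 342 at least 2-fold lower than on the lysine-deprived array, of 12198, and 323 and 298 after quantile normalization. PLK1 (2.33), SPRYD4 (2.21), RRAGB (2.11), TSPAN15 (2.08) and PARP10 (2.04) were higher on the leucine-deprived array. CRYGD (-2.77), ZNF853 (-2.44), FAIM2 (-2.31), DDX60 (-2.09) and LINC01566 (-2.08) were lower there. Over complete medium PLK1 and SPRYD4 differed mainly on the lysine-deprived array (-1.99 and -2.14, against 0.34 and 0.07 on the leucine-deprived array). CRYGD, ZNF853, FAIM2 and LINC01566 were at the floor in complete medium and near it on the leucine-deprived array (signals of 57.2, 58.2, 62.6 and 61.0, floor 56.7). RRAGB, TSPAN15, PARP10 and DDX60 went opposite ways on the deprived arrays over complete medium, which a choice by the largest leucine-minus-lysine difference favours. They were dim (level percentiles of 17.5 to 22.5), and all but PARP10 rest on 1 probe set. Among brighter genes 7 were higher and 17 lower. The next probe set went the same way in 29 of 65 higher genes (44.6%, 32.3 to 57.5) and 54 of 103 lower genes (52.4%, 42.4 to 62.4). The G2/M list was higher on the leucine-deprived array, with a median of 0.23, 21 of 25 members above 0 and percentile 99.98. Cytosolic synthetases (0.19, percentile 99.6), pluripotency genes (0.15, percentile 98.3) and ribosomal proteins (0.11, percentile 98.3) were also above the middle 95%, and the methionine cycle list (-0.15, percentile 2.30) below it; the ribosomal median was -0.01 after quantile normalization. Of the alternatives, 9 put the methionine cycle list inside, 5 the pluripotency, 4 the ribosomal and 3 the synthetase list. The other 22 lists lay inside.

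Control probe sets describe the RNA and the hybridisation. The signal of the 3′ end of ACTB over that of its 5′ end was 5.44 on the complete-medium array, 7.55 on the leucine-deprived array and 11.2 on the lysine-deprived array. For GAPDH the same ratio was 1.08, 1.23 and 1.25. The 18 hybridisation spike-in probe sets were higher than on the complete-medium array by a median of 0.64 on the leucine-deprived and 0.68 on the lysine-deprived array, and the 4 poly-A spike-in probe sets of the 3′ end by 0.38 and 0.31.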

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

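The normalizations and gene lists used here were planned; their use as tests of an explanation, the pooled shares of probe sets, the ATF4 probe set medians and the spike scaling were chosen after the results were seen, and the G2/M probe set median after the pattern was seen but before its own value. Several values came from probe sets outside the comparisons. The ratio of 3′ to 5′ ACTB signal was 7.55 on the leucine-deprived and 11.2 on the lysine-deprived array, above the 5.44 of the complete-medium array. Hybridisation spikes were 0.64 and 0.68 higher than on the complete-medium array. Of 3156 kept probe sets not named here, 47 were at least 2-fold higher and 13 at least 2-fold lower on both deprived arrays.

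The ATF4 target list was higher on both deprived arrays. Independent measurement noise is argued against by the next probe sets of its genes, which did not enter the list medians: over 23 genes their median was 1.16 and 0.94, above all random ones of like level. Brightness-dependent scaling is argued against by a list median that stayed at 1.14 or more relative to all genes after quantile or cyclic loess normalization. A single factor per array cannot move that relative value. With arrays scaled to the hybridisation spikes the list medians were 0.51 and 0.43, and the medians of all genes -0.63 and -0.68. The poly-A spikes differed by less (0.38 and 0.31), so these medians are no measure of total mRNA. A response of ATF4 targets to amino acid removal is a hypothesis that may account for the pattern. An unusual complete-medium culture, which both differences share, stays open, since there was 1 such array.

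Genes 2-fold apart between the deprived arrays were many. If dim probe sets were only noisy, the next probe set of a gene would go the same way about as often as not, and it did so in 83 of 168 genes (49.4%, exact 95% interval 41.6 to 57.2). Without a level filter the share was 55.7% (50.4 to 60.9), where 53.5% is expected because most next probe sets lay below 0. Without cross-hybridising or shared probe sets it was 59.6% (56 of 94, 49.0 to 69.6), where 50.2% is expected. The lowest share was 46.6% (39.4 to 53.9) with the floor at the 20th percentile, where 49.4% is expected. Noise therefore cannot be told apart from a true part. Among brighter genes the share was 10 of 16 (62.5%, 35.4 to 84.8), which is too few to decide. A response that differs between leucine and lysine was not tested otherwise.

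G2/M genes were lower on the lysine-deprived than on the leucine-deprived array. The next probe sets of 15 of these genes had a median of 0.39 (leucine minus lysine), above the middle 95% of random ones (-0.21 to 0.28) but not their highest (0.54), so independent noise stays open. The lysine-deprived array also had the highest ACTB ratio (11.2), and more 3′-biased cRNA could lower probe sets far from the 3′ end; probe positions were not used here, so this cannot be told apart from a slower cell cycle without lysine. The latter was not tested.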

How the results depend on the processing

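The counts among brighter genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group had 1 array. The ATF4 list medians ranged from 1.03 to 1.18 (leucine) and 1.06 to 1.15 (lysine) with percentile 100 throughout. Of list medians and named genes, 765 and 3302 values moved by less than their spread and 43 and 163 by more. For lists this spread was the bootstrap SD of the median over members. For genes it was the SD between probe sets of a gene (0.49 to 0.58), so a gene could move that far and count as unmoved. Of list percentiles, 821 kept their side of the middle 95%, 61 moved inside it and 12 outside. Most of the 821 lay inside it in the main setting too. Signal over background limits most counts. The floor at the 60th percentile also switches off the level filter (19775 genes kept), and its counts are lower because a call needs signal above the floor on both arrays.

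Genes 2-fold higher and lower over complete medium numbered 532 and 333 (leucine) and 463 lower (lysine) with a floor at the 20th percentile, 121 and 43 and 207 and 101 at the 60th, and 101 and 35 and 184 and 94 with the filter at the 70th percentile. Between the deprived arrays these settings gave 481 and 564, 77 and 87, and 74 and 71. At 1.5-fold the counts were 1148 and 734, 1619 and 1063, and 945 and 1129; at 3-fold 42 and 19, 83 and 24, and 32 and 46. Among brighter genes they were 53 and 4, 90 and 28, and 7 and 17. Higher and lower on both deprived arrays were 323 and 54 (floor at the 20th), 69 and 7 (floor at the 60th), 71 and 5 (filter at the 70th, r = 0.606) and 43 and 2 (brighter genes, r = 0.681).

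The share of next probe sets going the same way was, with the floor at the 60th percentile, 91.1% and 39.1% (leucine, higher and lower), 87.8% and 38.6% (lysine) and 31.6% and 72.1% (leucine against lysine). At that floor 74.8%, 74.3% and 26.6% of all next probe sets lay above 0 and the rest below, so unrelated probe sets would give uneven shares too. With the filter at the 70th percentile it was 93.1% and 100% (leucine, 31 genes in both directions together) and 86.0% and 81.8% (lysine, 79 together). Most of these genes were higher, so the 100% rests on very few. Without a level filter it was 74.1% and 34.9% (lysine) and 67.1% (leucine below lysine), where 63.5% lay above and 62.3% below 0, and 66.7% for the last without cross-hybridising or shared probe sets. Of the lists compared between the deprived arrays, 0 lay below the middle 95% under quantile normalization, either floor, the stricter filter, probe set means, the narrower probe sets or unmatched lists; 2 lay above with probe set means or the narrower probe sets, and 1 with unmatched lists.

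Few values were counted as reversed, and where no reason is given, their cause was not tested. In the main setting these genes were at least 2-fold apart, bounds included, and these lists stood apart. Sign changes of smaller values were not counted. Over the settings the pluripotency median ranged from -0.028 to 0.095 (leucine over complete). The ATF4 list median ranged from -0.024 to 0.095 (leucine minus lysine). Quantile normalization gave -0.0075 for ribosomal proteins and cyclic loess -1.58 for PAX3 (both leucine minus lysine). The floor at the 60th percentile gave 0.036 for the endoderm list (leucine), 0.0505 for HHEX (lysine), and -0.34 for PAX3 and -0.11 for TERT (leucine minus lysine); those of the endoderm list and TERT equal the medians of all genes at that floor. FGD2 was 0.42 and 0.88 with the floor at the 20th percentile and without cross-hybridising or shared probe sets, and 0.30 and 0.66 without a floor. Those narrower probe sets also gave -0.28 for ATF3 and 0.47 for IDI1 (lysine). Probe set means gave 0.0146 for the methionine cycle list (leucine minus lysine). Without ATF4 targets, transporters were -0.0907 (lysine) and serine, glycine and folate-cycle genes -0.0121 (leucine), because the members left out were the higher ones. Some named genes lost their probe sets: 38 without the cross-hybridising or shared ones, 7 with the floor at the 20th percentile, 6 with cyclic loess, 5 without a floor and 1 with quantile normalization.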

Other observations

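Metallothionein genes, which bind zinc and copper, were higher on both deprived arrays. This list was chosen after the values were seen. All 8 measured members lay above 0, with a median of 0.75 after leucine and 0.88 after lysine removal. MT1M was highest, at 1.52 and 1.94, and MT1X was 0.49 and 0.60 higher. The members are near-identical in sequence, so their probe sets are not independent of each other.

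Of the 24 brighter genes outside the ATF4 list that were 2-fold higher on both arrays, the following were picked after their values were seen. ASS1, the argininosuccinate synthetase gene, was 1.33 and 1.27 higher after leucine and lysine removal, and PRODH, the proline dehydrogenase gene, 1.23 and 1.04. GRPEL2, a mitochondrial co-chaperone gene, was 1.44 and 1.49 higher. ID4, an inhibitor of differentiation factors, was 1.25 and 1.29 higher, and the transcriptional corepressor gene BCOR 1.15 and 1.46.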
